A study of Homo sapiens with 10 samples.

How the data were processed

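RNA from 10 cultures of OVCAR-3, an established human ovarian adenocarcinoma cell line, was sequenced in 5 groups of 2 biological replicates. Control cells grew in standard culture. Day1 and Day3 cells were immobilized in silica gel for 24 hours and for 3 days. Extracted cells had survived 3 days of immobilization and then recovered for 2 weeks, and Treated cells had survived 24 hours of 0.5 uM cisplatin, a platinum drug that crosslinks DNA, without immobilization, and then recovered for 2 weeks. The labels describe total RNA extraction with column kits and standard Illumina library protocols, with library selection and strand setting not given in the sources used here.

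The deposited table holds TPM, transcript abundances corrected for length and scaled to a fixed total, per gene and library, made by the authors with Trimmomatic for trimming, STAR for alignment to GRCh38 and Cufflinks for quantification, per the labels. Tool versions and the gene annotation release are not given in the sources used here. TPM are therefore shares, and the libraries sum to nearly the same value. The table holds 349 blank lines and 58313 gene entries, of which 91 share an Ensembl identifier with an earlier entry, and TPM were summed per identifier to 58222 genes. GENCODE release 29, used for biotypes and GRCh38 positions, held 57959 of these identifiers (99.55%), and 54666 of them had the same symbol. XIST and genes of the Y chromosome were left out when genes were chosen for naming or flagged. TPM carry no read counts, so the depth of each library is unknown, no counting interval can be given for a single value, and an exact 0 may be a failed estimate as well as an absent transcript.

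Genes with at least 1 TPM in at least 2 libraries (15167) were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 coefficient per group, a mean-variance trend and 5 residual degrees of freedom, in a single fit of all 10 libraries. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are log2 differences of log2(TPM + 1), first group minus second, so that they understate the ratio of low TPM. Comparisons were Day1, Day3, Extracted and Treated against Control, Day3 against Day1, Extracted against Day3, and Treated against Extracted.

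33 gene lists for pathways, cell states and other cell types were fixed before the data were examined, as were the tests, the filter, the alternatives and the rule for naming genes. The rule named, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among those with a group mean of at least 5 TPM and non-overlapping groups, with clone-like and small-RNA names left out. It further named the 3 called members with the largest change of each list described, or the 2 members with the highest TPM where none was called. The lists described were the 8 with the smallest camera p, those with at least 1 in 3 of their measured members called, and the other-cell-type and mitochondrial lists. Against Control it always named EGR1, MKI67, CDKN1A, VEGFA and MUC16, while CA9 and ABCB1, also on that list, stayed below the filter. Some genes that the rule named are not reported here. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and again with a correlation estimated per list. Camera compares a list with all other tested genes, so a list can be called with few of its members called, or in a direction other than its median.

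Alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, rescaling by the median of ratios to the geometric mean, a fit of the 2 compared groups alone, a 2-fold minimum, the replicate number as a block, and each library left out in turn with the lone library of its group assumed to vary like the other groups. Nuclear protein-coding genes alone, rescaled to an equal sum, and removal of small-RNA genes with the rest rescaled, were added after the share of such genes per library had been seen. Overlaps of calls were set against independent lists, and correlations and covariances of fold changes against 100 simulations of unchanged groups with shared libraries. After the overlaps had been seen, the 2 libraries of the shared group were also divided between the 2 comparisons, 1 each, in both ways, with 4 residual degrees of freedom. The calls were also tested on simulated data in which 200 of the 15167 genes were changed. There, 90% to 95% of 2-fold changes and 37% to 61% of 1.5-fold changes were recovered, and 3 to 15 unchanged genes were called. Groups of 2 libraries allow no test for a deviating replicate and no regrouping of samples that could reach a small p. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 served for tables and plots. Splicing, variants and raw reads were not analysed here.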

Results

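TPM were measured in 10 libraries of OVCAR-3 cells, from 2 separate cultures per group. Values are means ± SD in TPM (n = 2 per group) and fold changes are log2. P values are adjusted, from limma for genes and camera for gene lists. Sequencing depth is unknown for every library. Between 13896 and 14173 genes per library reached 1 TPM. Pearson correlations of replicates across genes, which are not independent replicates, were 0.988 in Control, 0.983 in Day1, 0.991 in Day3, 0.989 in Extracted and 0.984 in Treated. The 1st principal component (39.1% of the variance) placed the Day1 and Day3 libraries at one end and the Treated libraries at the other. Control lay between them.

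The 13 mRNAs of the mitochondrial genome made up 16.7% and 15.8% of the TPM in the Control libraries, 2.29% and 3.92% on Day1, 5.97% and 7.61% on Day3, 11.1% and 10.7% in Extracted, and 10.8% and 10.4% in Treated cells. Small-RNA genes, which throughout include the mitochondrial rRNAs, held 14.7% of the TPM of Treated replicate 2. They held 3.21% of Extracted replicate 1 and 0.20% to 1.24% of the other 8 libraries. A larger share for these genes leaves less for the rest. The median fold change of all tested genes was 0.12 in Day1 and -0.15 in Treated against Control, and -0.13 in Treated against Extracted. It stayed within 0.10 of 0 in the other 4 comparisons.

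**Figure D1:**
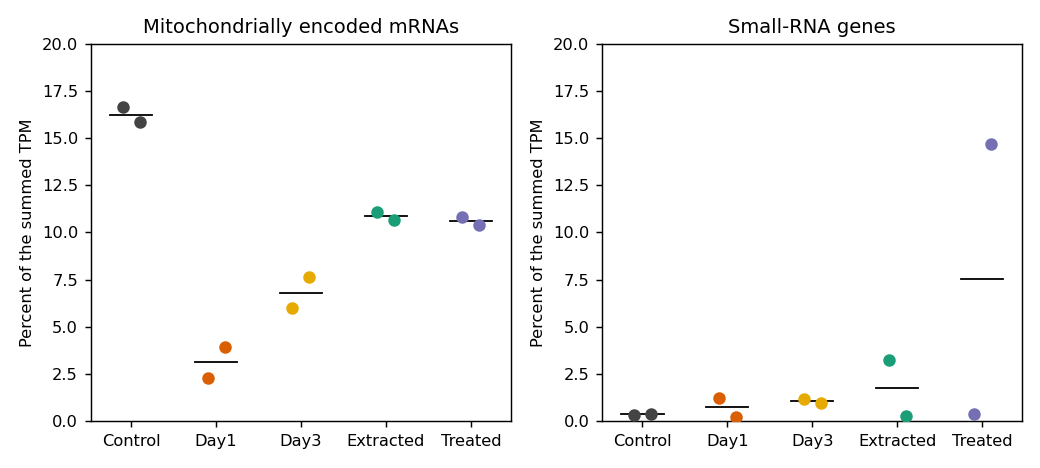
Percent of each library's summed TPM held by the mRNAs of the mitochondrial genome (left) and by small-RNA genes (right), with 1 point per library and the mean of the 2 libraries of each group as a line. Both Day1 libraries lie at 3.92% or less for mitochondrial mRNAs, and Treated replicate 2 stands at 14.7% for small-RNA genes.

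The comparison of Day1 with Control asked how the cells differed after 24 hours in silica gel. ATF3, a stress-induced transcription factor, rose from 13.9 ± 0.394 to 181.1 ± 53.9 TPM (n = 2, fold change 3.58, adjusted p = 2.09e-05). CALCB, which encodes a calcitonin gene-related peptide, rose by 2.99 to 106.8 ± 16.9 TPM and the chemokine CXCL8 by 2.65 to 79.2 ± 34.8. DDIT3, the stress factor CHOP, rose by 2.49 to 145 ± 36.7, the protease inhibitor SERPINE2 by 2.49 to 52.9 ± 19.8 and the antiviral gene IFIT1 by 2.44 to 9.36 ± 4.34. All 13 mitochondrially encoded mRNAs fell, with a median fold change of -2.42 (adjusted p = 5.4e-23, and adjusted p = 0.395 with an estimated correlation). MT-ND6 (ENSG00000198695, mitochondrial genome from 14149 to 14673) fell from 243.2 ± 28.8 to 13.5 ± 1.32 TPM (fold change -4.07, adjusted p = 1.25e-05). MT-ND2 fell from 9679 ± 67.4 to 1578 ± 555, and MT-ATP8, which overlaps MT-ATP6, from 47980 ± 3838 to 7903 ± 2735. MT-ND6 lies on the strand opposite the other mRNA genes of that genome and the strand setting is unknown, so its level is less certain. The nuclear RNA NEAT1 fell from 104.7 ± 4.21 to 14.7 ± 3.18 TPM, the poly(A)-binding protein gene PABPC1L from 41.7 ± 4.95 to 4.67 ± 1.00, and the tropomyosin TPM2 from 13.01 ± 1.44 to 1.32 ± 0.166.

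Of the 18 genes of the ATF4 and amino-acid response list, 14 rose and 0 fell on Day1 (16 adjusted over the list alone, adjusted p = 5.8e-09). SESN2, a stress-induced regulator of mTORC1, rose by 1.89 and TRIB3, a pseudokinase induced by ATF4, by 1.83. Among 21 interferon-stimulated genes, 16 rose (16 adjusted over the list alone, adjusted p = 7.75e-08), with IFI6 at 14.6 ± 4.34 against 2.30 ± 0.934 TPM (fold change 2.25) and IFI44L at a fold change of 1.95. In the list of NF-kB and inflammatory cytokine genes 11 of 18 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 3.45e-05). CXCL2 rose by 2.19 and CXCL3 by 1.71, though reads are partly shared between these paralogs. Immediate-early genes gave 14 rises and 1 fall of 19 (the same counts adjusted over the list alone, adjusted p = 0.000161). FOSL1, a subunit of AP-1, rose by 2.33 and KLF4 by 1.20. EGR1, the member that fell, went from 19.2 ± 0.358 to 9.19 ± 0.127 TPM (fold change -0.99, adjusted p = 0.00186). Hypoxia-response genes gave 9 rises and 2 falls of 19 (10 and 2 adjusted over the list alone, adjusted p = 0.00376). DDIT4 rose by 2.14, BNIP3 by 1.42, STC2 by 1.30 and VEGFA, the angiogenic growth factor, by 0.95 to 58.9 ± 6.17 TPM. With an estimated correlation the adjusted p of each of these 5 lists was 0.395.

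In the mitotic list 8 of 25 genes fell and 0 rose with limma on Day1 (9 adjusted over the list alone, adjusted p = 1.51e-07), with MKI67, a proliferation marker, at 37.1 ± 10.0 against 65.0 ± 4.15 TPM (fold change -0.82, adjusted p = 0.0116). AURKB fell by 0.65 and TOP2A fell by 0.60. Falls in this list numbered 18 under median-of-ratios scaling and 20 among nuclear protein-coding genes rescaled alone. Of 24 DNA replication genes 7 fell (7 adjusted over the list alone, adjusted p = 2.8e-06), among them UHRF1, E2F1 and TK1 with fold changes of -0.70, -0.49 and -0.48, against 13 and 17 falls under these scalings. Of 12 targets of YAP, the transcriptional coactivator that responds to cell shape and stiffness, 7 fell (7 adjusted over the list alone, adjusted p = 8.78e-07). CTGF went from 94.1 ± 1.44 to 43.6 ± 0.961 TPM (fold change -1.09), CRIM1 fell by 0.94 and F3, tissue factor, fell by 1.14. In the DNA repair list 5 of 27 genes fell (5 adjusted over the list alone, adjusted p = 0.000588), and 10 and 12 under the same scalings. The 3 measured metallothioneins, MT1F, MT1X and MT2A, fell with fold changes of -0.95, -0.74 and -0.72 (adjusted p = 0.00214), though reads are partly shared within this family. With an estimated correlation the adjusted p was 0.522 for DNA repair and 0.395 for the other 4 lists of this paragraph.

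CDKN1A, the cell-cycle inhibitor p21, rose on Day1 from 4.57 ± 1.58 to 20.9 ± 2.05 TPM (fold change 2.00, adjusted p = 0.000236). The p53 target list as a whole was not called, with 7 of 22 members higher (8 adjusted over the list alone, adjusted p = 0.0864). Apoptosis regulators gave 7 rises and 1 fall of 19 (8 and 1 adjusted over the list alone, adjusted p = 0.00591). The pro-apoptotic genes PMAIP1, BBC3 and BIK rose by 1.43, 1.34 and 1.23. Autophagy and lysosome genes gave 7 rises of 18 (9 adjusted over the list alone, adjusted p = 0.00652), with SQSTM1 at 480.9 ± 81.7 against 204.6 ± 10.8 TPM, MAP1LC3B up by 0.98 and GABARAPL1 by 0.92. Ribosomal protein genes gave 21 rises of 28 (25 adjusted over the list alone, adjusted p = 1.18e-07). They were small in size, with RPS6 at 0.60, RPL30 at 0.52 and RPL32 at 0.50, and numbered 10 under median-of-ratios scaling and 7 among nuclear protein-coding genes. Processed pseudogenes share reads with this family. Replication-dependent histone genes gave 5 rises of 10 (8 adjusted over the list alone, adjusted p = 0.00191), with HIST1H2BD up by 1.16, HIST1H4H by 1.06 and HIST1H1E by 1.22. With an estimated correlation the adjusted p of the 4 lists called in this paragraph was 0.395.

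Several lists had calls in both directions and were not called as lists on Day1. Epithelial genes gave 5 rises and 2 falls of 20 (adjusted p = 0.235), with the tight-junction genes CLDN4 up by 1.12 and OCLN by 0.96 and RAB25 up by 0.64. Endoplasmic reticulum chaperone and unfolded-protein genes gave 5 rises (DNAJB9 0.81, HERPUD1 0.76) and 4 falls (SDF2L1 -0.74) of 16 (adjusted p = 0.386), with a negative median and a positive mean fold change. Glycolytic enzymes gave 4 rises (ALDOC 0.68, LDHA 0.39) and 2 falls (GPI -0.70) of 17 (adjusted p = 0.805), with the camera direction opposite to a median of 0.09. Of these rises 0 were left with limma under median-of-ratios scaling or among nuclear protein-coding genes, where 2 and 4 fell. Fatty-acid synthesis genes gave 3 rises (FADS1 0.67, FADS2 0.49) and 2 falls (FASN -0.98) of 11 (adjusted p = 0.832). NRF2 and antioxidant genes gave 5 rises (GCLC 0.74, OSGIN1 0.67, SLC7A11 0.64) and 2 falls of 19 (adjusted p = 0.907). Dormancy and quiescence genes gave 6 rises (CDKN1A, HES1 0.95) and 2 falls (THBS1 -1.35) of 20 (adjusted p = 0.847), with 4 and 7 falls under these scalings. Drug efflux transporters gave 1 rise (ABCA3 0.85) and 2 falls (ABCC5 -0.51, ABCC1 -0.45) of 8 (adjusted p = 0.647). Nuclear respiratory-chain genes gave 2 rises and 1 fall of 24 (median 0.10, adjusted p = 0.805), and heat-shock genes 1 and 1 of 14 (adjusted p = 0.386). Stem-cell-associated genes gave 3 rises of 15 (adjusted p = 0.832) and platinum handling genes 2 rises of 12 (adjusted p = 0.386). MUC16, which encodes the CA-125 antigen, stood at 43.8 ± 7.03 against 47.1 ± 13.4 TPM (fold change -0.08, adjusted p = 0.774).

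In all, 3132 of the 15167 genes were called in Day1 against Control, 2180 higher and 952 lower (69.6% higher). Median-of-ratios scaling gave 1542 higher and 1734 lower (47.1% higher) and nuclear protein-coding genes alone, rescaled, 1037 higher and 2014 lower, both of which turned the balance. Of the calls 461 had at least a 2-fold change, 225 higher and 236 lower. The count was 1040 without Control replicate 1, 965 without Control replicate 2 and 1515 without Day1 replicate 1. Across the 4 fits that left out a Control or a Day1 library, 680 genes kept their call in each. Of the 70 named genes called, 49 were among them. MKI67, AURKB, TOP2A, TK1, F3, DNAJB9, LDHA, ALDOC, GCLC, SLC7A11, MT1F, MT2A, ABCC5, ABCC1 and RPS6 lost their call without Control replicate 1 and also without Control replicate 2. E2F1, SDF2L1, OSGIN1, MT1X, ABCA3 and HIST1H1E lost theirs without at least 1 of the 4 libraries. Among the lists, mitochondrial mRNAs kept 13 falls in each fit that left out a library, and the ATF4 list kept between 11 and 15 rises. Mitotic falls ranged from 0 (without Control replicate 2) to 12, and replication falls from 1 (without Control replicate 2) to 11. YAP target falls ranged from 4 (without Control replicate 1) to 7, and immediate-early rises from 6 (without Control replicate 1) to 14. Interferon rises ranged from 9 (without Control replicate 2) to 17, and ribosomal rises from 3 (without either Control library) to 24.

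**Figure D2:**
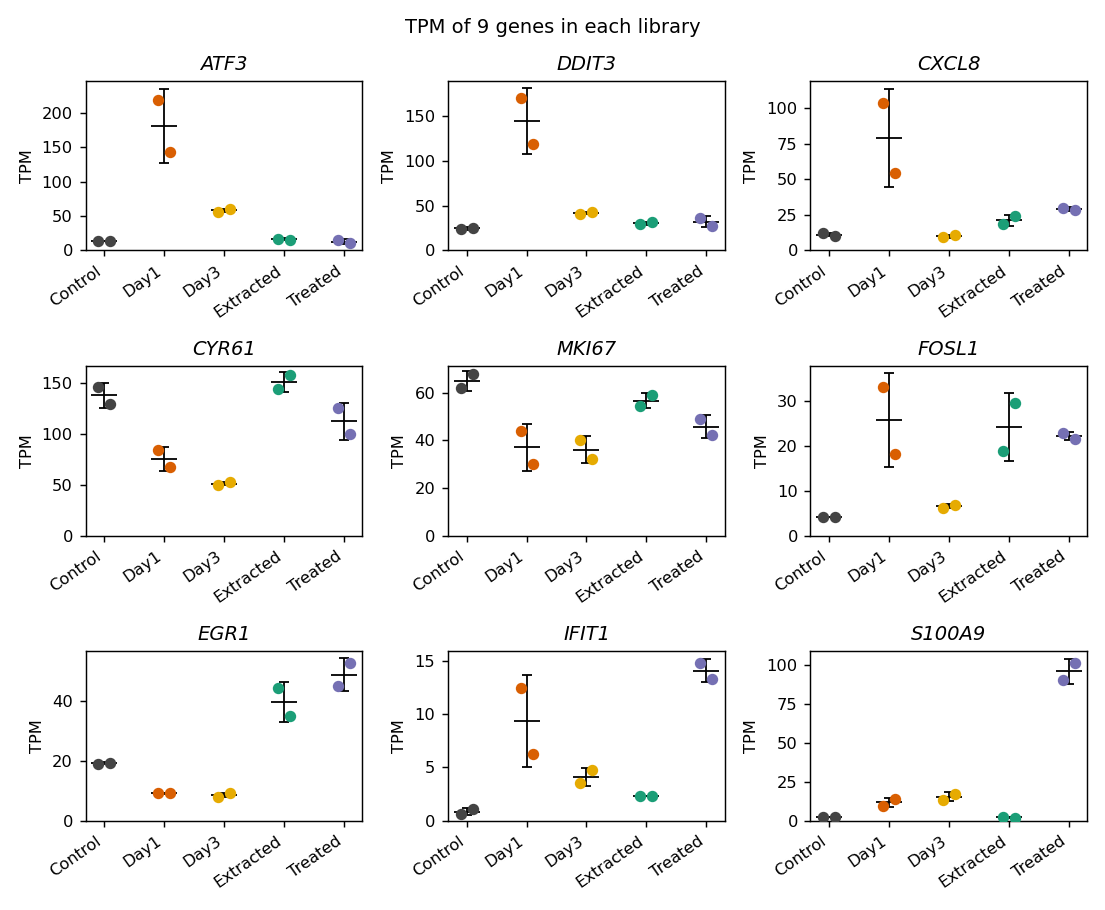
TPM of 9 genes in each library by group, with 1 point per library and the mean ± SD of the 2 libraries as a line and bars. ATF3, DDIT3 and CXCL8 are highest on Day1, CYR61 and MKI67 are lowest on Day1 and Day3, and S100A9 reaches 90.3 TPM or more in both Treated libraries.

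The comparison of Day3 with Control asked how the cells differed after 3 days in silica gel. S100A8 and S100A9, which encode the subunits of calprotectin, rose to 7.47 ± 0.788 from 0.493 ± 0.421 TPM and to 15.3 ± 2.87 from 2.38 ± 0.256 TPM (fold changes 2.53 and 2.26, adjusted p = 0.000296 and 0.000263). IGFBP5, an insulin-like growth factor binding protein, rose from 6.36 ± 0.75 to 37.5 ± 2.96 TPM (fold change 2.39), and the intermediate filament VIM from 1.75 ± 0.131 to 11.6 ± 0.186 (2.20). ATF3 rose to 58.3 ± 2.27 (2.00) and LCN2, an iron-sequestering secreted protein, from 16.6 ± 0.868 to 68.8 ± 10.8 (1.98). MT-ND6 fell to 40.9 ± 2.28 TPM (fold change -2.54), NEAT1 to 20.5 ± 2.77 (-2.30), and BMPER, a modulator of BMP signalling, from 11.6 ± 2.10 to 1.65 ± 0.923 (-2.28). TPM2 fell to 2.00 ± 0.156 (-2.22) and PABPC1L to 9.20 ± 1.04 (-2.06). GOLGA8A fell by 2.03, with its level uncertain because near-identical copies share reads.

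On Day3, 8 of 12 YAP targets fell (8 adjusted over the list alone, adjusted p = 3.44e-09). CYR61 went from 138.2 ± 12.1 to 51.2 ± 1.65 TPM (fold change -1.41) and ANKRD1 from 38.4 ± 5.87 to 9.88 ± 0.884 (-1.85). In the mitotic list 8 of 25 fell (12 adjusted over the list alone, adjusted p = 6.28e-11). MKI67 fell to 36.1 ± 5.61 TPM (fold change -0.84, adjusted p = 0.0194), with CENPE, a kinetochore motor, at -0.92 and TOP2A at -0.76. Mitotic falls on Day3 numbered 18 under median-of-ratios scaling and 22 among nuclear protein-coding genes. Of 24 replication genes 4 fell (5 adjusted over the list alone, adjusted p = 4.77e-06), including UHRF1, CCNE1 and E2F1 (-0.67, -0.49 and -0.45), and 9 and 14 under these scalings. All 13 mitochondrial mRNAs fell (13 adjusted over the list alone, median -1.32, adjusted p = 1.28e-15). Ribosomal protein genes gave 10 rises of 28 (26 adjusted over the list alone, adjusted p = 1.95e-10), with RPS6, RPL30 and RPL37 at 0.49, 0.44 and 0.44. Interferon-stimulated genes gave 9 rises of 21 (12 adjusted over the list alone, adjusted p = 3.53e-05), including IFI44L by 1.70 and IFIT1 and IFI6 by 1.49 each. Histone genes gave 3 rises of 10 (6 adjusted over the list alone, adjusted p = 0.00187; HIST1H2BD 0.82, HIST1H2AC 0.81, HIST1H4H 0.65). Autophagy and lysosome genes gave 4 rises of 18 (6 adjusted over the list alone, adjusted p = 0.00588; SQSTM1 0.77, WIPI1 0.53, LAMP2 0.38). MT1F (-1.02) was the 1 metallothionein of 3 that fell (2 adjusted over the list alone, adjusted p = 0.00684). Each of these 9 lists had adjusted p = 0.416 with an estimated correlation.

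Ovarian carcinoma markers gave 5 rises of 12 on Day3 (5 rises and 1 fall adjusted over the list alone, adjusted p = 0.00588, and adjusted p = 0.643 with an estimated correlation). WFDC2, which encodes the serum marker HE4, rose from 532.5 ± 13.8 to 1169 ± 53.1 TPM (fold change 1.13, adjusted p = 0.000368), and the kallikreins KLK6 and KLK7 rose by 1.09 and 0.98. The ATF4 list gave 5 rises and 1 fall of 18 (the same counts adjusted over the list alone, adjusted p = 0.042). NUPR1 rose by 1.13 and DDIT3 by 0.74, and the amino-acid transporter SLC7A5 fell by 0.98. DNA repair genes gave 4 falls of 27 (4 adjusted over the list alone, adjusted p = 0.00588) and nuclear respiratory-chain genes 2 rises of 24 (2 adjusted over the list alone, adjusted p = 0.0078). Each of these last 3 lists had adjusted p = 0.78 with an estimated correlation. CDKN1A rose by 1.05 to 10.3 ± 0.613 TPM and EGR1 fell by 1.07. VEGFA (fold change -0.02, adjusted p = 0.948) and MUC16 (0.29, adjusted p = 0.321) were not called.

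In Day3 against Control 1489 genes were called, 786 higher and 703 lower (52.8% higher, against 40.2% under median-of-ratios scaling). Nuclear protein-coding genes alone, rescaled, gave 458 higher and 1449 lower. At least a 2-fold change was seen in 280 calls, 82 higher and 198 lower (29.3% higher). The count was 252 without Control replicate 1, 302 without Control replicate 2, 216 without Day3 replicate 1, and 269 without Day3 replicate 2. It was 920 and 931 without Extracted replicates 1 and 2, and 2254 and 2251 without Treated replicates 1 and 2. In the 4 fits that left out a Control or a Day3 library, 157 genes kept their call in each. Among them were 21 of the 44 named genes called, including S100A8, S100A9, IGFBP5, VIM, ATF3, LCN2, NEAT1, CYR61, ANKRD1, WFDC2, KLK6, IFI6, SLC7A5 and EGR1. MKI67, CENPE, TOP2A, UHRF1, CCNE1, E2F1, F3, DDIT3, MT1F, KLK7, WIPI1, LAMP2, HIST1H2BD and the ribosomal genes lost their call in all 4. At least 1 of the 4 ended the call of NUPR1, IFI44L, IFIT1, SQSTM1, MT-ATP8, HIST1H4H and CDKN1A. Mitotic and ribosomal calls both went to 0 without any 1 of those 4 libraries and reached 13 and 24 without a Treated library. YAP target falls were 3 without any 1 of the 4, and mitochondrial falls 3 without Day3 replicate 1. Interferon rises were 2 without Day3 replicate 2, and ovarian marker rises 2 without Control replicate 1 or a Day3 library.

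The comparison of Day3 with Day1 asked what differed between 24 hours and 3 days of immobilization. CXCL8 fell from 79.2 ± 34.8 to 10.0 ± 1.21 TPM (fold change -2.80, adjusted p = 0.00298) and CALCB from 106.8 ± 16.9 to 16.1 ± 1.63 (-2.65, adjusted p = 4.05e-05). The chemokine CCL20 fell to 1.39 ± 0.0238 (-2.08) and the lysosomal membrane gene LAMP3 to 8.97 ± 0.602 (-1.77). FOSL1 fell to 6.57 ± 0.395 (-1.77) and AREG, a ligand of the EGF receptor, to 4.95 ± 0.849 (-1.76). In the NF-kB list 12 of 18 fell (15 adjusted over the list alone, adjusted p = 5.06e-14) and in the ATF4 list 10 of 18 (15 adjusted over the list alone, adjusted p = 5.06e-14). DDIT3 stood at 41.8 ± 1.38 against 145 ± 36.7 TPM (-1.75), with TRIB3 at -1.41 and GDF15 at -1.42. Immediate-early genes gave 8 falls of 19 (14 adjusted over the list alone, adjusted p = 9.45e-11), among them ATF3 (-1.59) and IER3 (-1.29). All 13 mitochondrial mRNAs rose (13 adjusted over the list alone, median 1.15, adjusted p = 1.49e-20), with MT-ND6 at 1.53, MT-ND5 at 1.32 and MT-ATP8 at 1.26. These 4 lists had adjusted p = 0.388 with an estimated correlation.

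Hypoxia-response genes gave 7 falls, with DDIT4, STC2 and ADM at -1.25, -1.13 and -1.02, and 1 rise of 19 (9 and 1 adjusted over the list alone, adjusted p = 0.00171). Apoptosis regulators gave 2 falls of 19 (5 adjusted over the list alone, adjusted p = 0.00298), and cholesterol synthesis genes 1 rise of 22 (2 adjusted over the list alone, adjusted p = 0.000499). Ovarian carcinoma markers gave 0 calls of 12 with limma (1 adjusted over the list alone, adjusted p = 0.000213), with WFDC2 at a fold change of 0.07 and PAX8 at 0.27. These 4 lists had adjusted p = 0.489 with an estimated correlation. Interferon-stimulated genes gave 1 fall of 21, DDX58 at -0.64 (7 adjusted over the list alone, adjusted p = 0.000363, and adjusted p = 0.518 with an estimated correlation). Nuclear respiratory-chain genes gave 0 calls of 24 with limma (0 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.676 with an estimated correlation). SELENOP, a selenium transport protein, rose from 41.3 ± 17.4 to 115.8 ± 6.12 TPM (fold change 1.53, adjusted p = 0.0182).

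In Day3 against Day1 356 genes were called, 100 higher and 256 lower (28.1% higher, against 39.7% of 554 calls under median-of-ratios scaling and 38.5% among nuclear protein-coding genes). At 2-fold or more there were 114 calls, and 5 in a fit of these 2 groups alone. The count was 37 without Day1 replicate 1, 837 without Day1 replicate 2, and 12 and 15 without Day3 replicates 1 and 2. It was 168 and 164 without Control replicates 1 and 2, and 174 and 171 without Extracted replicates 1 and 2. Only 7 genes kept their call in each of the 4 fits that left out a Day1 or a Day3 library, and of the 23 named genes called these held CXCL8, CALCB and DDIT3. Without a Day3 library, mitochondrial rises, immediate-early falls and hypoxia falls went to 0, NF-kB falls to 1, and ATF4 falls to 2 without Day3 replicate 1. Without Day1 replicate 1 the mitochondrial rises went to 1 and the NF-kB falls to 2.

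Between the 2 time points, 1045 genes were called in the same direction against Control, 548 higher and 497 lower, and 4 in opposite directions. Independent lists would share 157.1, though the same Control libraries enter both comparisons. The fold changes correlated at r = 0.67 across genes, against 0.50 in simulations of unchanged groups with shared Control libraries, and their covariance exceeded the simulated value by 0.109. With 1 Control library given to each time point, in either way, r was 0.52 and 0.42 and the overlap 179 and 170. The overlap was 198 and 209 without Control replicates 1 and 2, and 180 and 228 without Day3 replicates 1 and 2. It was 639 and 645 without Extracted replicates 1 and 2, and 1627 without either Treated library.

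The comparison of Extracted with Control asked how cells that survived immobilization and recovered for 2 weeks differed. Of its calls, 55 were also called in that direction on Day3. FOSL1 was higher at 24.2 ± 7.62 against 4.11 ± 0.0464 TPM (fold change 2.27, adjusted p = 0.005), as was AREG at 26.4 ± 5.50 against 5.44 ± 0.264 (2.07). Also higher were PI3, the protease inhibitor elafin, at 32.1 ± 9.81 against 8.58 ± 0.419 (1.76), the growth factor GDF15 (1.51), the hyaluronan receptor CD44 at 34.0 ± 10.3 against 11.2 ± 0.801 (1.49) and the transcription factor SOX3 (1.39). TMPRSS15, which encodes enteropeptidase, was lower at 13.2 ± 1.99 against 41.5 ± 0.411 TPM (fold change -1.59, adjusted p = 0.00243). The imprinted RNA H19 was lower at 30.4 ± 4.43 against 101 ± 14.2 (-1.70), as were WNT11 at 14.5 ± 0.198 against 50.8 ± 15.8 (-1.70), SELENOP (-1.56) and AMOT, a regulator of YAP (-1.55). The readthrough gene TMEM189-UBE2V1 was listed lower (-1.65), with reads shared with its parent genes.

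Immediate-early genes gave 4 rises and 1 fall of 19 in Extracted cells (the same counts adjusted over the list alone, adjusted p = 6.25e-05). FOS stood at 1.35, DUSP5 at 1.24 and EGR1 at 39.6 ± 6.68 against 19.2 ± 0.358 TPM (1.00, adjusted p = 0.0142). Ribosomal protein genes gave 5 rises of 28 (14 adjusted over the list alone, adjusted p = 5.49e-12), including RPL13 by 0.50 and RPL18 by 0.49. The ATF4 list gave 1 rise of 18, GDF15 (7 adjusted over the list alone, adjusted p = 6.45e-05). Of the mitochondrial mRNAs 0 of 13 were called with limma while 8 were lower adjusted over the list alone (median -0.54, adjusted p = 4.39e-06). MT-ATP8 stood at 27205 ± 1158 against 47980 ± 3838 TPM (fold change -0.82, adjusted p = 0.0709), with MT-CO2 at -0.39. These 4 lists had adjusted p = 0.804 with an estimated correlation. The NF-kB list gave 1 rise of 18, CXCL1 at 0.85 (6 adjusted over the list alone, adjusted p = 0.00467), and interferon-stimulated genes 1 of 21, ISG15 at 0.63 (1 adjusted over the list alone, adjusted p = 0.0405). Nuclear respiratory-chain genes gave 1 rise of 24, ATP5O at 0.44 (3 adjusted over the list alone, adjusted p = 0.0405), and replication genes 0 of 24 with limma (0 adjusted over the list alone, adjusted p = 0.0405; MCM4 -0.19, RRM2 -0.28). The 4 lists from NF-kB on had adjusted p = 0.938 with an estimated correlation. Under median-of-ratios scaling the adjusted p of the interferon and nuclear respiratory-chain lists was 0.0603 and 0.0609, against 0.0405 for both.

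Among mesenchymal genes 1 rose and 4 fell of 13 (1 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.058). MMP2 stood at 1.33, fibronectin (FN1) at 86.0 ± 9.89 against 213.1 ± 8.38 TPM (-1.30) and TAGLN at -1.29. MT2A, at 123.1 ± 11.9 against 53.7 ± 3.94 TPM (1.18), was the 1 of 3 metallothioneins called (1 adjusted over the list alone, adjusted p = 0.0692 for the list). MKI67 (fold change -0.19, adjusted p = 0.618), CDKN1A (-0.56, adjusted p = 0.156), VEGFA (-0.10, adjusted p = 0.702) and MUC16 (0.35, adjusted p = 0.326) were not called.

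In Extracted against Control 302 genes were called, 130 higher and 172 lower, 68 of them at 2-fold or more. Median-of-ratios scaling gave 324 higher and 323 lower, and nuclear protein-coding genes alone, rescaled, 241 higher and 791 lower (23.4% higher). The count was 7 and 2 without Control replicates 1 and 2, and 19 and 8 without Extracted replicates 1 and 2. It was 90 without either Day3 library, 457 without Day1 replicate 2 and 654 without either Treated library. Only TMPRSS15 kept its call in each of the 4 fits that left out a Control or an Extracted library, so the call of the other 24 named genes ended without at least 1 of them. FN1 lost its call without Control replicate 2 alone. Immediate-early rises went to 0 without either Control library and to 1 without Extracted replicate 2. Ribosomal rises went to 0 without any Control, Day3 or Extracted library and to 13 without a Treated library.

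The comparison of Extracted with Day3 asked what changed between the end of immobilization and 2 weeks of recovery. NEAT1 rose from 20.5 ± 2.77 to 133.7 ± 2.04 TPM (fold change 2.65, adjusted p = 4.05e-05), the cytokine IL18 from 20.1 ± 0.846 to 116.5 ± 12.2 (2.47), and the laminin chain LAMA3 from 77.9 ± 0.739 to 374.7 ± 51.4 (2.25). The nitric oxide synthase NOS1 rose to 15.8 ± 1.74 (2.51), TPM2 to 13.9 ± 0.525 (2.32) and the carboxypeptidase CPA4 to 16.1 ± 0.618 (2.26). IGFBP5 fell from 37.5 ± 2.96 to 2.79 ± 0.391 TPM (-3.35, adjusted p = 2e-06), and WNT11 from 109.6 ± 1.83 to 14.5 ± 0.198 (-2.83). SELENOP fell from 115.8 ± 6.12 to 15.4 ± 2.13 (-2.84) and HLA-DRA, an MHC class II chain, from 11.8 ± 0.176 to 1.42 ± 0.122 (-2.41). S100A9 fell to 2.19 ± 0.232 (-2.35) and the peptide transporter SLC15A2 to 2.56 ± 1.30 (-2.32).

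YAP targets gave 8 rises of 12 (8 adjusted over the list alone, adjusted p = 8.14e-08, and adjusted p = 0.632 with an estimated correlation). CYR61 stood at 151.4 ± 9.94 against 51.2 ± 1.65 TPM (1.55), with F3 at 1.53 and ANKRD1 at 1.41. Metallothioneins gave 3 rises of 3 (3 adjusted over the list alone, adjusted p = 0.00137), with MT2A at 1.85, MT1F at 1.07 and MT1X at 0.59. Histone genes gave 6 falls of 10 (8 falls and 1 rise adjusted over the list alone, adjusted p = 0.000793), including HIST1H1C, HIST1H2AC and HIST1H4H at -1.02, -1.01 and -0.94. Metallothioneins and histones had adjusted p = 0.632 with an estimated correlation. Mitotic genes gave 8 rises of 25 (14 adjusted over the list alone, adjusted p = 8.14e-08), with CENPE, TOP2A and HMMR at 1.13, 0.72 and 0.71, and 19 rises under either of the 2 scalings. Mitochondrial mRNAs gave 6 rises of 13 (11 adjusted over the list alone, adjusted p = 2.28e-07), with MT-ND6, MT-CO3 and MT-ND3 at 1.74, 1.03 and 0.97. The NF-kB list gave 6 rises of 18 (7 rises and 2 falls adjusted over the list alone, adjusted p = 0.00415), including the cytokines IL6 at 2.13, LIF at 1.31 and CXCL8 at 1.01. Immediate-early genes gave 7 rises and 3 falls of 19 (9 and 3 adjusted over the list alone, adjusted p = 0.00703). EGR1 stood at 39.6 ± 6.68 against 8.63 ± 0.792 TPM (2.07), with FOS at 1.95 but ATF3 at -1.75. These last 4 lists had adjusted p = 0.869 with an estimated correlation.

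Ovarian carcinoma markers gave 6 falls of 12 in Extracted against Day3 cells (7 falls and 1 rise adjusted over the list alone, adjusted p = 0.0273). CRABP2 stood at 159.4 ± 8.48 against 513.5 ± 22.3 TPM (-1.68), with KLK7 at -1.18 and WFDC2 at -0.95. Interferon-stimulated genes gave 5 falls of 21 (5 adjusted over the list alone, adjusted p = 0.0441), and heat-shock genes 3 rises of 14 (3 adjusted over the list alone, adjusted p = 0.0273; CHORDC1 0.66, CRYAB 0.62, BAG3 0.36). Replication genes gave 3 rises of 24 (1 adjusted over the list alone, adjusted p = 0.0273). These 4 lists had adjusted p = 0.869 with an estimated correlation. CDKN1A fell from 10.3 ± 0.613 to 2.71 ± 0.0763 TPM (-1.61). The p53 target list, with PLK3 at 1.29 and GDF15 at 1.19, had 4 rises and 4 falls of 22 and was not called (adjusted p = 0.952). Dormancy and quiescence genes gave 2 rises (THBS1 1.55) and 6 falls (BHLHE41 -1.16) of 20 (adjusted p = 0.703). Stem-cell-associated genes gave 2 rises (CD44 1.62) and 3 falls (ALDH1A1 -1.05, LGR5 -0.95) of 15 (adjusted p = 0.712).

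In Extracted against Day3 2599 genes were called, 955 higher and 1644 lower (36.7% higher, against 51.9% under median-of-ratios scaling, which turned the balance). Nuclear protein-coding genes alone gave 1504 higher and 1506 lower. Of the 2599, 533 had at least a 2-fold change. The count was 852 and 1086 without Day3 replicates 1 and 2 and 1110 and 877 without Extracted replicates 1 and 2. In each of these 4 fits 661 genes kept their call, 33 of the 47 named genes called among them. TOP2A, HMMR, CXCL8, CHORDC1, CRYAB, BAG3, MT1F, MT1X, KLK7, ALDH1A1, LGR5, GDF15, MT-CO3 and MT-ND3 were not. YAP target rises stayed between 6 and 8 and histone falls between 5 and 7. Mitotic rises ranged from 2 (without Day3 replicate 1 or 2 or Extracted replicate 2) to 14, and NF-kB rises from 2 (without Day3 replicate 1 or Extracted replicate 2) to 8. Mitochondrial rises ranged from 1 (without Day3 replicate 1 or an Extracted library) to 12, and ovarian marker falls from 2 (without a Day3 library or Extracted replicate 2) to 6.

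Of the 1489 genes called in Day3 against Control, 986 (66.2%) were called in the opposite direction in Extracted against Day3, 517 that had been higher and 469 that had been lower. Independent lists would give 129.5. Because both comparisons hold the Day3 libraries, unchanged groups already give r = -0.50 across genes, and the observed value was r = -0.74 with a covariance beyond the simulated one by -0.121. With the Day3 libraries divided, 1 each for Control and for Extracted, the fold changes against Day3 correlated at r = 0.56 in either way. A return gives a positive sign there. Of the Day3 calls, 55 were called in the same direction in Extracted against Control, 29 higher and 26 lower, and 44 in the opposite direction. The 986 hold 4 of these 55 and all 44. Independent lists would give 14.7 in the same direction. Here r was 0.21 against 0.50 in unchanged groups, with a covariance that exceeded the simulated one by 0.0064. With the Control libraries divided, r was -0.02 and 0.04 and the genes with a kept direction numbered 3 and 1. The number that turned (986) fell without any 1 Control, Day3 or Extracted library. So did the number of Day3 calls it was drawn from, so the lower counts alone do not measure a weaker return. The number that kept its direction (55) also fell without any 1 of these libraries, and it rose without a Treated library.

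The comparison of Treated with Control asked how cells that survived cisplatin and recovered for 2 weeks differed. S100A9 (ENSG00000163220, chromosome 1 from 153357854 to 153361027) was higher at 95.9 ± 7.85 against 2.38 ± 0.256 TPM (fold change 4.84, adjusted p = 2.7e-06), and its neighbour S100A8 (from 153390032 to 153391188) at 24.1 ± 4.56 against 0.493 ± 0.421 (4.09, adjusted p = 6.39e-06). PI3 was higher at 141 ± 2.84 against 8.58 ± 0.419 TPM (3.89) and AREG at 89.4 ± 17.2 against 5.44 ± 0.264 (3.80). The acute-phase gene SAA1 was higher at 12.6 ± 3.79 against 0.317 ± 0.213 (3.35) and the retinol dehydrogenase gene DHRS9 at 12.9 ± 1.46 against 0.423 ± 0.00192 (3.28). TMPRSS15 was lower at 4.57 ± 0.0782 against 41.5 ± 0.411 TPM (-2.93, adjusted p = 2.81e-06) and the chloride channel gene CLIC5 at 8.46 ± 0.834 against 67.9 ± 6.99 (-2.86). The neuronal transcription factor gene NPAS3 was lower at 1.18 ± 0.14 against 12.9 ± 0.0403 (-2.67) and SAMD11 at 2.41 ± 0.777 against 19.6 ± 5.64 (-2.59). The short entries TUG1_3 and PART1_2, annotated as miscellaneous RNAs, were also called lower (-4.52 and -3.05). However, TUG1_3 was listed at 2.53e-06 and 11.2 TPM in the Treated libraries, and PART1_2 at 0 and 2.49e-20 TPM, so that no ratio is given. Small-RNA genes held 0.39% and 14.7% of Treated replicates 1 and 2.

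Of 21 interferon-stimulated genes 17 were higher in Treated than in Control cells (17 higher and 1 lower adjusted over the list alone, adjusted p = 4.81e-17, and adjusted p = 0.485 with an estimated correlation). BST2, which encodes tetherin, stood at 17.4 ± 2.29 against 1.13 ± 0.349 TPM (3.12). IFIT1 stood at 14.1 ± 1.09 against 0.832 ± 0.329 (3.05) and IFI27 at 38.7 ± 1.64 against 5.48 ± 1.16 (2.62). The NF-kB list gave 7 rises of 18 (7 adjusted over the list alone, adjusted p = 2.7e-06), including CXCL2 at 2.46, CXCL1 at 1.71 and ICAM1 at 1.43. Immediate-early genes gave 7 rises (FOSL1 2.19, DUSP5 1.74, FOS 1.36, EGR1 1.30) and 3 falls of 19 (9 and 4 adjusted over the list alone, adjusted p = 0.000325). Mitotic genes gave 18 falls of 25 (21 adjusted over the list alone, adjusted p = 1.89e-06). FOXM1, a transcription factor of the G2 phase, stood at 48.8 ± 4.76 against 88.1 ± 0.717 TPM (-0.84), and DLGAP5 and CCNA2 at -0.75 each. Replication genes gave 15 falls of 24 (19 adjusted over the list alone, adjusted p = 7.95e-06), with MCM4, CDC6 and RRM2 at -0.77, -0.73 and -0.71. The median of all genes stood at -0.15, and under median-of-ratios scaling, which removes that shift, the falls numbered 15 in the mitotic and 11 in the replication list. Ribosomal protein genes gave 12 rises of 28 (14 adjusted over the list alone, adjusted p = 4.42e-10; RPL18 0.57, RPS6 0.53, RPLP2 0.49), and 23 under median-of-ratios scaling. These 5 lists had adjusted p = 0.748 with an estimated correlation.

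Mitochondrial mRNAs gave 8 falls of 13 in Treated cells (9 adjusted over the list alone, adjusted p = 0.00577, and adjusted p = 0.811 with an estimated correlation), with MT-ND6, MT-ND5 and MT-ND2 at -1.17, -1.10 and -0.93. There were 3 falls under median-of-ratios scaling. Cholesterol synthesis genes gave 8 falls of 22 (11 falls and 1 rise adjusted over the list alone, adjusted p = 0.0499, and adjusted p = 0.748 with an estimated correlation). DHCR7 stood at -0.74 and ACAT2 at -0.58. Under median-of-ratios scaling the list gave 2 rises and 3 falls and its call was lost (adjusted p = 0.175).

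Other lists had members called in Treated cells without a call of the list. Ovarian carcinoma markers gave 5 rises and 3 falls of 12 (adjusted p = 0.0595). KLK6 stood at 1.50 and the folate receptor FOLR1 at 1.47, with MUC16 at 107.7 ± 5.51 against 47.1 ± 13.4 TPM (1.20) and WT1 at 14.4 ± 1.36 against 49.6 ± 4.61 (-1.72). CD44 was higher at 79.2 ± 8.17 against 11.2 ± 0.801 TPM (2.72), while ALDH1A1 fell by 1.23 and LGR5 fell by 0.94. Their stem-cell-associated list had 2 rises and 3 falls of 15 (adjusted p = 0.894), with a negative median and an upward camera direction. Mesenchymal genes gave 4 rises (MMP2 1.64) and 4 falls (TAGLN -1.86, LOX -1.43) of 13 (adjusted p = 0.393), with a positive median and a negative mean. Epithelial genes gave 5 rises (KRT19 1.04, CLDN3 0.77) and 5 falls (TJP1 -0.87) of 20 (adjusted p = 0.186). DNA repair genes gave 10 falls of 27 (14 adjusted over the list alone, adjusted p = 0.0595), including XRCC3 at -1.05, RAD52 at -0.90 and FANCC at -0.85. Heat-shock genes gave 2 rises (the small heat-shock proteins CRYAB 1.35 and HSPB1 1.07) and 5 falls (HSP90AA1 -0.59) of 14 (adjusted p = 0.423). NRF2 and antioxidant genes gave 3 rises (FTH1 0.97) and 7 falls (TXNRD1 -1.02, ME1 -0.98) of 19 (adjusted p = 0.656). FTH1 has processed pseudogenes that share reads.

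YAP targets gave 2 rises (AXL 1.56) and 4 falls (AJUBA -1.30, ANKRD1 -1.03) of 12 in Treated cells (adjusted p = 0.435). Dormancy and quiescence genes gave 3 rises and 7 falls (GAS1 -1.74, BMP7 -1.05, THBS1 -1.01) of 20 (adjusted p = 0.676). Apoptosis regulators gave 1 rise and 6 falls (BMF -1.30, XIAP -0.79) of 19 (adjusted p = 0.682). Hypoxia-response genes gave 4 rises (NDRG1 0.99, DDIT4 0.95) and 4 falls (P4HA2 -0.79, VEGFA -0.49) of 19 (adjusted p = 0.263). Histone genes gave 5 falls of 10 (adjusted p = 0.0865; HIST2H2BE -0.74, HIST1H2BK -0.66, HIST1H2BC -0.45), and nuclear respiratory-chain genes 1 rise and 7 falls of 24 (adjusted p = 0.186; NDUFA4 -0.52, NDUFS1 -0.48, UQCRC1 -0.42). Fatty-acid synthesis genes gave 1 rise (ACSS2 0.79) and 3 falls (ME1, ACLY -0.36) of 11 (adjusted p = 0.435). Of the 3 metallothioneins MT2A rose, at 152 ± 8.77 against 53.7 ± 3.94 TPM (1.48; adjusted p = 0.0868 for the list). Platinum handling genes gave 3 falls of 12 (adjusted p = 0.676) and drug efflux transporters 2 falls of 8 (adjusted p = 0.384). MKI67 (fold change -0.50, adjusted p = 0.0648) and CDKN1A (0.27, adjusted p = 0.311) were not called.

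In Treated against Control 3715 genes were called, 953 higher and 2762 lower (25.7% higher), of which 562 had at least a 2-fold change. Median-of-ratios scaling gave 1875 higher and 1754 lower (51.7% higher), and nuclear protein-coding genes alone 1320 higher and 3029 lower (30.4% higher). The count was 1723 without Control replicate 1 and 1315 without Control replicate 2. Without Treated replicate 1 it was 4183 with 15.5% higher, and without Treated replicate 2 it was 2583 with 42.6% higher. In each of the 4 fits that left out a Control or a Treated library 1059 genes kept their call, 60 of the 81 named genes called among them. HSP90AA1, RPS6, NDUFA4, NDUFS1, ACAT2, ACLY, FANCC, XIAP, THBS1, UQCRC1 and VEGFA lost it without either Control library. TUG1_3, ACSS2, TJP1, CLDN3, LGR5, RAD52, MT-ND5, MT-ND2 and HIST1H2BC lost it without at least 1 of the 4 libraries. Interferon rises stayed between 12 and 17. Mitotic falls ranged from 10 (without Control replicate 1) to 22, and replication falls from 6 (without Control replicate 2) to 21. NF-kB rises ranged from 4 (without Control replicate 2) to 8, and ribosomal rises from 2 (without Control replicate 1) to 21 (without Treated replicate 2). Mitochondrial falls ranged from 1 (without Control replicate 2) to 11 and cholesterol falls from 2 (without either Control library or Treated replicate 2) to 10.

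**Figure D3:**
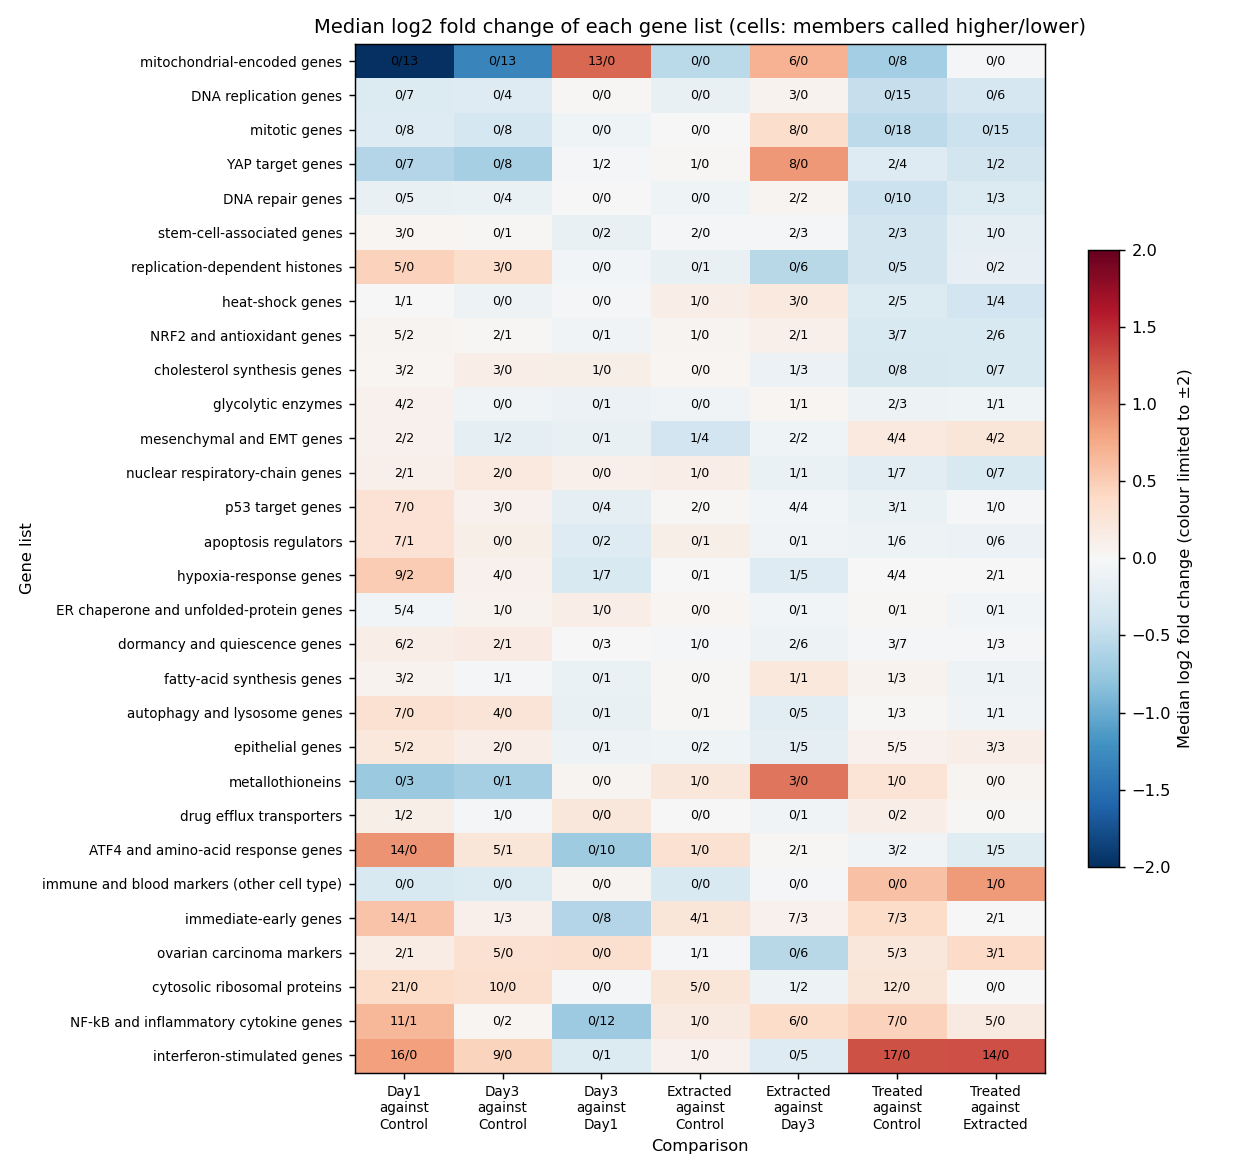
Median log2 fold change of the measured members of each gene list (colour, limited to 2 in either direction) in each comparison, with the numbers of members called higher and lower printed in the cells. All 13 mitochondrially encoded mRNAs are called lower on Day1 and Day3, and 16, 9 and 17 of 21 interferon-stimulated genes are called higher on Day1, on Day3 and in Treated cells.

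Extracted and Treated cells, which each survived a stress and recovered for 2 weeks, shared most of the calls of the former. Of the 302 genes called in Extracted cells, 261 (86.4%) were called in the same direction in Treated cells, 110 higher and 151 lower, and 3 in the opposite direction. PI3, AREG, FOSL1, CD44, FOS, DUSP5, EGR1, MMP2 and MT2A were higher in both, and TMPRSS15 and TAGLN were lower in both. H19 was not among them, with a fold change of -1.70 in Extracted cells, nor was FN1, at 209.2 ± 28.8 TPM in Treated against 213.1 ± 8.38 in Control cells. The change was larger in Treated cells for 185 of the 261 genes (70.9%), with median absolute fold changes over the 261 of 0.75 and 0.98, and 97 of the 302 differed in the direct test of Treated against Extracted. Independent lists would share 39.5 calls, though the same Control libraries enter both comparisons. Across genes r was 0.57 against 0.50 in simulated unchanged groups with shared Control libraries, and the covariance exceeded theirs by 0.067. With 1 Control library given to each, r was 0.37 and 0.31, and 1 of 2 and 5 of 9 Extracted calls were shared. The overlap was 5 and 2 without Control replicates 1 and 2, and 15 and 7 without Extracted replicates 1 and 2. It was 85 without either Day3 library, and 458 and 470 without Treated replicates 1 and 2.

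**Figure D4:**
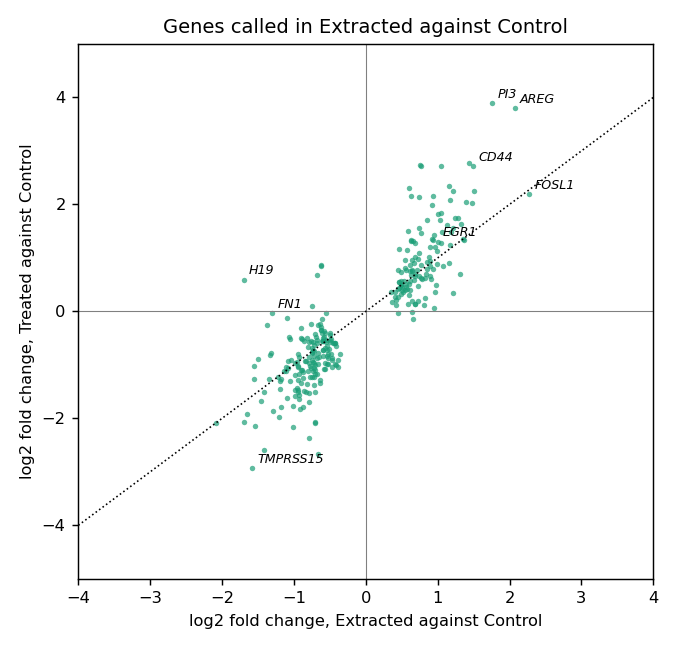
Log2 fold changes against Control in Extracted (horizontal axis) and Treated cells (vertical axis) of the 302 genes called in Extracted against Control, with 1 point per gene and a dotted line where both are equal. Of these genes 261 were called in the same direction in Treated cells, and H19 and FN1 were not among them.

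The comparison of Treated with Extracted asked how the survivors of cisplatin differed from those of immobilization after equal recovery. S100A9 was higher in Treated cells at 95.9 ± 7.85 against 2.19 ± 0.232 TPM (fold change 4.92, adjusted p = 2.28e-06) and S100A8 at 24.1 ± 4.56 against 0.739 ± 0.141 (3.84, adjusted p = 5.25e-05). The interferon-induced genes IFITM1 and IFI27 were higher at 24.3 ± 3.90 against 2.58 ± 0.217 TPM (2.82) and 38.7 ± 1.64 against 5.57 ± 1.88 (2.63). SAA1 (2.61) and DHRS9 (2.60) followed. CLIC5 was lower at 8.46 ± 0.834 against 38.8 ± 5.03 TPM (-2.07) and NPAS3 at 1.18 ± 0.14 against 7.71 ± 0.542 (-2.00). ID2, an inhibitor of basic helix-loop-helix factors, was lower at 63.6 ± 1.16 against 189.5 ± 4.04 (-1.56), as were the guidance gene NTNG1 at -1.72, filaggrin (FLG) at -1.65 and DOC2B at -1.62.

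Interferon-stimulated genes gave 14 rises of 21 in Treated against Extracted cells (16 adjusted over the list alone, adjusted p = 2.04e-19, and adjusted p = 0.376 with an estimated correlation), including BST2 at 2.55 and IFI44L at 2.32. Mitotic genes gave 15 falls of 25 (20 adjusted over the list alone, adjusted p = 2.44e-08), with CENPE, CDC20 and CCNA2 at -0.82, -0.68 and -0.67. Replication genes gave 6 falls of 24 (13 adjusted over the list alone, adjusted p = 0.000239), with MCM4, CDC6 and CDC45 at -0.58, -0.57 and -0.55. Nuclear respiratory-chain genes gave 7 falls of 24 (12 adjusted over the list alone, adjusted p = 0.000285; NDUFA4 -0.67, NDUFB8 -0.46, SDHC -0.43) and 0 with limma under median-of-ratios scaling. Cholesterol synthesis genes gave 7 falls of 22 (14 adjusted over the list alone, adjusted p = 0.00114; IDI1 -0.59, NSDHL -0.47) and 2 under that scaling. The NF-kB list gave 5 rises of 18 (6 rises and 1 fall adjusted over the list alone, adjusted p = 0.000502; CXCL2 1.47, CXCL3 1.28, CXCL1 0.86). Epithelial genes gave 3 rises and 3 falls of 20 (5 and 3 adjusted over the list alone, adjusted p = 0.00618). MUC1 stood at 60.9 ± 6.28 against 23.0 ± 1.43 TPM (1.36), KRT19 at 1.08 and TJP1 at -0.70, and rises numbered 6 under median-of-ratios scaling and 8 among nuclear protein-coding genes. Ovarian carcinoma markers gave 3 rises (KLK6 0.92, MUC16 0.85) and 1 fall (WT1 -1.35) of 12 (5 and 1 adjusted over the list alone, adjusted p = 0.00618). The 7 lists from mitotic to ovarian had adjusted p = 0.626 with an estimated correlation.

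FN1 was higher at 209.2 ± 28.8 against 86.0 ± 9.89 TPM (1.27), as were TGFBI (1.24) and SPARC (0.98). The mesenchymal list that holds them gave 4 rises and 2 falls of 13 (5 and 2 adjusted over the list alone, adjusted p = 0.0135, adjusted p = 0.554 with an estimated correlation, and 0.0681 under median-of-ratios scaling). NRF2 and antioxidant genes gave 2 rises and 6 falls of 19 (adjusted p = 0.229), with the thioredoxin reductase gene TXNRD1 at -1.25, ME1 at -0.81 and GCLM at -0.73. The ATF4 list gave 1 rise (NUPR1 0.99) and 5 falls (SLC7A5 -0.78, CHAC1 -0.75) of 18 (adjusted p = 0.19). Heat-shock genes gave 1 rise (HSPB1 0.73) and 4 falls of 14 (adjusted p = 0.059, and 0.0117 under median-of-ratios scaling), among them CHORDC1 at -0.60 and HSPA1B at -0.56, whose reads are shared with a near-identical copy.

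Of the immune and blood markers only 3 of 11 were measured, and CD14, at 1.26 ± 0.0773 against 0.254 ± 0.00413 TPM in Treated against Extracted cells (0.85, adjusted p = 0.0283), was the 1 called in any comparison. Here 2 were called adjusted over the list alone (adjusted p = 0.0135 for the list, adjusted p = 0.536 with an estimated correlation, and 0.0605 under median-of-ratios scaling). PTPRC, LYZ and CD3E stayed at or below 0.484 TPM in every library and HBB was listed at 0. Of the fibroblast markers 2 of 10 were measured and 0 were called with limma in any comparison (adjusted p = 0.235 in Day1 and 0.779 in Treated against Control). Of the 7 endothelial markers 0 passed the filter, so that list was not tested.

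In Treated against Extracted 1836 genes were called, 491 higher and 1345 lower (26.7% higher), while median-of-ratios scaling gave 963 higher and 719 lower (57.3% higher), which turned the balance. Nuclear protein-coding genes alone gave 942 higher and 1076 lower (46.7% higher). Of the calls, 212 had at least a 2-fold change, and a fit of these 2 groups alone gave 129 calls. The count was 246 and 166 without Extracted replicates 1 and 2, 3143 without Treated replicate 1, and 731 without Treated replicate 2. It was 1069 and 1070 without Control replicates 1 and 2, and 1091 and 1093 without Day3 replicates 1 and 2. In each of the 4 fits that left out an Extracted or a Treated library 130 genes kept their call, among them 18 of the 48 named genes called, which were S100A9, S100A8, IFITM1, IFI27, DHRS9, CLIC5, NPAS3, NTNG1, FLG, DOC2B, ID2, BST2, IFI44L, TXNRD1, MUC1, FN1, WT1 and KLK6. Interferon rises stayed between 10 and 16. Mitotic, replication, NF-kB, cholesterol and nuclear respiratory-chain calls went to 0 without 1 of the Extracted libraries and reached 23, 15, 6, 12 and 17 in other fits.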

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

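In this part the limit of 10000 TPM for unfiltered entries was chosen only after results were seen. So was the choice to set median-of-ratios scaling, a setting fixed earlier, beside the balance of calls. The test without small-RNA genes was added after their shares had been seen.

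Entries that did not pass the filter on low values, and so entered no comparison, reached more than 10000 TPM in a single library while being listed at 0 in Control. The miRNA gene MIR4655 was listed at 68345 TPM, the U6 pseudogene RNU6-698P at 20288 TPM and the miRNA gene MIR98 at 14672 TPM in Treated replicate 2. A Y_RNA entry stood at 29295 TPM in Extracted replicate 1, and the non-coding gene AL162413.1 at 14629 TPM in Treated replicate 1.

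Called in opposite directions on Day1 and Day3 against Control were 4 genes, each with adjusted p = 0.00593 in Day3 against Day1 (limma), a test that their selection by opposite calls makes no independent support. SMAD7, an inhibitor of TGF-beta signalling, went from 22.5 TPM in Control to 32.6 on Day1 and 14.3 on Day3 (log2 fold change of Day3 against Day1 -1.14). IER3, an immediate-early gene, stood at 55.6, 84.1 and 33.5 TPM (-1.29) and ID4, an inhibitor of basic helix-loop-helix factors, at 49.5, 68.5 and 31.3 TPM (-1.10). The non-coding gene AL138760.1 moved the other way at 0.926, 0 and 3.57 TPM (2.18). With 2 libraries per group each of these differences rests on 4 libraries.

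Treated cells had more lower than higher calls against Control, 2762 against 953, so that 25.7% were higher. Small-RNA genes held 14.7% of the TPM of Treated replicate 2 and 0.39% of Treated replicate 1, and with these genes removed and the rest rescaled 42.7% of the calls were higher, while 42.6% were higher without Treated replicate 2 and 15.5% without Treated replicate 1. Median-of-ratios scaling gave 51.7%, but it removes the typical shift by construction (median -0.003), so it cannot tell scaling from a true fall. The small-RNA share of 1 library may explain part of the excess. Against small-RNA genes as the whole account, nuclear protein-coding genes alone, rescaled, still gave 30.4% higher, a setting that also removes the mitochondrial mRNAs, whose share was larger in Control. Why 1 Treated library holds so much small-RNA signal stays open, as does a lower level of many transcripts in cisplatin survivors, which TPM without read counts or a spike-in cannot measure.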

How the results depend on the processing

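Depth is unknown for every library, so how far it limits the calls cannot be given. Removal of small-RNA genes, nuclear protein-coding genes alone and divided libraries were added after results had been seen. Each comparison rests on 2 libraries per group and 5 residual degrees of freedom shared by all groups. Of 353 results for named genes, 351 kept their direction and their side of the threshold with a pseudocount of 0.1, 342 under median-of-ratios scaling, 256 without a filter and 278 in a fit of the 2 compared groups alone. Of those that could be tested, 345 of 347 did so with a filter at 5 TPM, 319 of 328 among nuclear protein-coding genes and 345 of 351 without small-RNA genes, and 0 changed direction under any of these settings with limma. With a pseudocount of 0.1 and a filter at 5 TPM every count of calls and overlap stayed within 1.5 times the reported one.

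With the replicate number as a block the counts were 3199 for Day1, 1409 for Day3, 243 for Extracted and 3713 for Treated against Control, 340 for Day3 against Day1, 2560 for Extracted against Day3 and 1775 for Treated against Extracted. Residual correlations of equal replicate numbers lay between -0.022 and 0.087 over 10 pairs of groups, 2 of them negative, so the numbers showed little pairing.

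In fits of the 2 compared groups alone, which hold 4 libraries each, the counts were 1894 for Day1, 2585 for Day3, 653 for Extracted and 1645 for Treated against Control, 5 for Day3 against Day1, 4079 for Extracted against Day3 and 129 for Treated against Extracted. Limited to 2-fold changes, a stricter rule by construction, they were 461, 280, 68, 562, 114, 533 and 212 in that order, and the overlaps were 174 for Day1 and Day3, 164 for Day3 calls that turned in Extracted, 10 for Day3 calls that kept their direction and 52 for Extracted and Treated.

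Without a filter, where more genes are tested, 832 genes were called in Day3 and 99 in Extracted against Control, 89 in Day3 against Day1 and 1018 in Treated against Extracted, and the 4 overlaps were 601, 570, 24 and 74 in the same order. Scaling raised several counts, and the cause was not tested. Day3 against Day1 gave 554 calls under median-of-ratios scaling, 574 among nuclear protein-coding genes and 572 without small-RNA genes, Extracted against Control 647, 1032 and 636, the overlap of Extracted and Treated 519, 820 and 514, and the Day3 calls that kept their direction in Extracted 143, 220 and 157. The overlap of Day1 and Day3 was 1574 without small-RNA genes.

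With the 2 shared Control libraries divided, 1 for each comparison in either way, the overlap of Day1 and Day3 was 179 and 170, that of Extracted and Treated 1 and 5, and the Day3 calls that kept their direction in Extracted 3 and 1. With the Day3 libraries divided, 149 and 147 Day3 calls turned in Extracted. These fits set a group of 2 against a lone library, so fewer calls follow from their construction as well.

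With an inter-gene correlation estimated per list, camera called 0 lists in each of the 7 comparisons, against 15 for Day1, 13 for Day3, 8 for Extracted and 8 for Treated against Control, 10 for Day3 against Day1, 11 for Extracted against Day3 and 10 for Treated against Extracted at the preset correlation. At an unadjusted p under 0.05 the estimated correlation left 1, 2, 0, 1, 4, 2 and 2 lists in that order. List calls therefore depend on the preset correlation, and the cause was not tested.

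Leaving out 1 library, which leaves fewer samples and a lone one in its group, gave between 965 (without Control replicate 2) and 4106 calls (without Treated replicate 2) for Day1 against Control, 216 (Day3 replicate 1) and 2254 (Treated replicate 1) for Day3, 2 (Control replicate 2) and 654 (Treated replicate 2) for Extracted, and 1315 (Control replicate 2) and 4183 (Treated replicate 1) for Treated against Control. It gave 12 (Day3 replicate 1) to 837 (Day1 replicate 2) for Day3 against Day1, 852 (Day3 replicate 1) to 3206 (Treated replicate 2) for Extracted against Day3, and 166 (Extracted replicate 2) to 3143 (Treated replicate 1) for Treated against Extracted. The overlap of Day1 and Day3 ranged from 180 (Day3 replicate 1) to 1627 (Treated replicate 2), the Day3 calls that turned in Extracted from 154 (Day3 replicate 1) to 1419 (Treated replicate 1), those that kept their direction from 2 (Control replicate 2) to 178 (Treated replicate 2), and the overlap of Extracted and Treated from 2 (Control replicate 2) to 470 (Treated replicate 2). Removing a library of a group outside the comparison also moved counts, through the spread estimated from all groups. Without 1 library the fold changes of 4 uncalled genes changed sign. MUC16 in Day1 against Control ranged from -0.37 (Control replicate 1) to 0.21 (Control replicate 2), with 0.08 without Day1 replicate 1. VEGFA in Day3 against Control ranged from -0.049 (Day3 replicate 2) to 0.016 (Day3 replicate 1), WFDC2 in Day3 against Day1 from -0.067 (Day1 replicate 1) to 0.20 (Day1 replicate 2), and CDKN1A in Treated against Control from -0.019 (Control replicate 1) to 0.57 (Control replicate 2).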

Other observations

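The tests of explanations in this part, and the choice to describe the genes that stayed changed from Day3 to Extracted, were made only after results were seen, as was the division of the Control libraries.

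Of the 55 genes called in the same direction on Day3 and in Extracted cells against Control, 26 were lower at both times, and those named here were picked by hand. Another 44 Day3 calls were called in the opposite direction in Extracted against Control. The collagen gene COL5A2 went from 26.8 ± 2.05 TPM in Control to 7.90 ± 1.03 on Day3 and 9.11 ± 0.974 in Extracted cells (fold changes -1.65 and -1.46, adjusted p = 0.000567 and 0.005), and FN1 had fold changes of -1.51 and -1.30. The Wnt effector LEF1 stood at -1.17 and -1.21, the Hedgehog effector GLI2 at -0.99 and -0.99, the gap junction gene GJA1 at -0.67 and -1.02 and the protease TMPRSS15 at -0.86 and -1.59. The mesenchymal list, which holds FN1, was not called on Day3 (adjusted p = 0.0611) or in Extracted cells (adjusted p = 0.058). Without any 1 Control, Day3 or Extracted library far fewer genes kept their direction, and without a Treated library more did. With 1 Control library given to Day3 and the other to Extracted, in either way, 3 and 1 genes kept their direction and r across genes was -0.02 and 0.04, so how far the 55 rest on the shared Control libraries is open.

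The other 29 were higher at both times. SLPI, a secreted protease inhibitor, went from 400.6 ± 18.1 TPM in Control to 928.5 ± 7.99 on Day3 and 670.4 ± 12 in Extracted cells (fold changes 1.21 and 0.74, adjusted p = 0.000745 and 0.0209), PI3 had fold changes of 1.27 and 1.76, and KLK6 of 1.09 and 0.59. Among the 29 were also 5 ribosomal protein genes with smaller changes, from 0.34 to 0.44 on Day3 and from 0.35 to 0.56 in Extracted cells. Of the 55 genes, 50 were also called in the same direction in Treated against Control, among them all that are named here except FN1, though the same 2 Control libraries enter all 3 comparisons.

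Mitochondrially encoded mRNAs were lower on Day1 than in Control, with a median fold change of -2.42 over 13 genes (from -4.07 to -2.05), and mitochondrial rRNAs were listed lower too (MT-RNR2 at 628 and 816 TPM against 2415 and 2405, MT-RNR1 at 125 and 156 against 559 and 589). Against a few other transcripts taking more of the total, all other tested genes had a median of 0.12, and against a fall of all respiratory-chain transcripts, the 24 nuclear members had a median of 0.10. A rise of most other transcripts while mitochondrial RNA stayed the same would also place the 13 genes -2.54 from all genes, and with shares alone and 0 spike-in entries this cannot be told apart from a fall of mitochondrial RNA. Less capture of RNA kept inside organelles, the nucleus included, cannot be told apart from a response to immobilization either, because 3 of 5 nuclear non-coding RNAs were called lower (NEAT1 -2.77, MALAT1 -1.97, SNHG14 -0.57) and 2 were not (FTX -0.26, PVT1 -0.07), and how RNA was taken out of the gel, which only these groups had, is not given in the sources used here. Lower mitochondrial transcript levels may thus be part of the response to the gel, a hypothesis that spike-in RNAs and RNA taken out in another way would test.

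S100A9, S100A8 and 14 of 21 interferon-stimulated genes were called higher in Treated than in Extracted cells. Against blood or immune cells, PTPRC, LYZ and CD3E together reached at most 0.377 TPM in a Treated library while S100A9 was at 90.3 TPM or more, 239 times as high. CD14, however, was higher (1.26 against 0.254 TPM), with a call lost without any 1 of the 4 Treated and Extracted libraries, the immune and blood list was called on 3 measured members (adjusted p = 0.0135, but 0.536 with an estimated correlation and 0.0605 under median-of-ratios scaling), and CD68 stood at 6.21 and 7.46 TPM in Treated, 3.28 and 2.45 in Extracted and 5.21 and 2.59 in Control libraries, so the argument covers the rise of S100A9 and not these low-level markers. Against an effect of the scaling, 17 interferon-stimulated genes were called higher under median-of-ratios scaling. A lasting response to cisplatin and the outgrowth of cells that already expressed these genes are both candidate explanations, and neither was tested.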
